A study of Rattus norvegicus with 12 samples.

How the data were processed

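Rings of rat aorta (male rats of an inbred strain) were embedded in collagen or fibrin gel and cultured in serum-free medium, with 10 ng/ml recombinant rat TNF-alpha or without it, and RNA was taken at day 2, per the labels. Each sample combined 4 to 6 ring cultures, and 200 ng of total RNA was labelled for an Affymetrix whole-transcript array, per the labels' protocols. The 12 arrays form 4 groups of 3, called collagen control, collagen TNF, fibrin control and fibrin TNF. Groups and replicate numbers were taken from the sample titles, which name the replicates as biological; a tissue label that mentions collagen for the fibrin samples too was not used. Whether the replicates came from different animals is not stated, so p-values measure the spread between these samples.

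The deposited values are expression levels on a log2 scale, read as such from their range of 1.44 to 14.07, since the labels give neither the scale nor the summarisation and background method. Their column medians lay between 5.89 and 5.98. They were slightly higher in every collagen array (5.94 to 5.98) than in every fibrin array (5.89 to 5.93). Median centring therefore moves the comparison of the untreated matrices, by 0.06 (log2). How the values were normalized is not given in the sources used here. The submitters' processing notes name limma without a version. Scan dates, slides and gel lots are not given in the labels used here, so no batch could be tested. The number of arrays limits the precision: the median standard error of a log2 difference between groups was 0.09, and that of a difference of differences was 0.13.

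The value table holds 27342 probe sets on 12 arrays with 0 missing values. The probe annotation names 1 gene for 15097 probe sets and several for 323, and 11922 probe sets are unnamed here. Of the 1-gene probe sets, 15067 had a gene identifier found in a RefSeq gene table of assembly GRCr8, and 0 symbols differed from it. The probe set of highest mean over the 12 arrays stood for each gene, which left 14324 genes, 499 of them with more than 1 probe set. Genes of families with near-identical copies, such as Akr1c, Oas1, Mx, Ces1, RT1 and Scgb1b, can share probes and are uncertain as single genes. No genome positions are given, since the build of the array annotation is not stated.

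Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, all 12 arrays, two-sided), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Errors of log2 differences are standard errors of this fit, and errors of group levels are standard deviations with n = 3. The comparisons were TNF against control in each matrix, fibrin against collagen without and with TNF, and the difference of the TNF effect between matrices. In addition, 41 gene lists were fixed and tested with camera at a preset correlation of 0.01, with the correlation estimated from the data and fry as alternatives. Lists of cell type markers were read as expression in whole cultures, not as cell numbers. Samples, comparisons, lists, the rule for named genes and the alternatives, apart from those named as later choices, were fixed before the data were examined.

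Named genes were the 12 largest and 12 smallest log2 differences of each 2-group comparison among calls whose 3 + 3 arrays did not overlap, and the 10 largest and 10 smallest of the difference of TNF effects. From each list described, up to 6 called members of smallest adjusted p and up to 3 others could be named, and 27 genes were fixed by name, of which 22 were analysed. Symbols that are only locus numbers were to be skipped, which applied to 0 genes. The other genes fixed by name are not analysed here.

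Whether replicate numbers pair the samples was checked from the deviations of the arrays from their group means across genes. Arrays of the same number correlated at 0.13, 0.14 and 0.14 between collagen control and collagen TNF, and at 0.25, 0.14 and 0.16 between fibrin control and fibrin TNF, so the numbers were taken to pair samples within a matrix. Between matrices the values were 0.23, 0.08 and 0.13 without TNF, and 0.05, 0.03 and 0.14 with TNF. An array of another number correlated more highly only for replicate 2 without TNF (0.10 against 0.08). Pairing between matrices is thus possible, but none was taken. The main fit uses no pairing, within or between matrices. A fit with the replicate number as a block within each matrix was added after these correlations were seen.

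The fit was tested on simulated data made from the means and variances of the 14324 genes, with 200 changed genes. For the TNF effect in collagen it recovered 66.2% of genes changed by 0.5 on the log2 scale and 98.5% of those changed by 1, with 5.88% false calls. For the difference of the TNF effect it recovered 32.4% and 86.4%, with 3.33% false calls. Alternatives were quantile normalization, median centring, a filter on dim genes, only the groups compared, a trended and robust prior, array weights, the replicate block, other uses of probe sets, a 2-fold threshold and each array left out.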

Results

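Gene expression was measured in rat aortic rings, a culture model of vessel sprouting, after 2 days in collagen or fibrin gel with or without 10 ng/ml TNF-alpha, an inflammatory cytokine. The 12 arrays form 4 groups of 3. The groups separated along the first principal component (52.9% of the variance), with mean scores of -26.9 ± 2.22 (SD, n = 3) for collagen control, -4.99 ± 1.44 for collagen TNF, 9.71 ± 3.28 for fibrin control and 22.2 ± 3.14 for fibrin TNF. The second component (10.7%) set collagen TNF (-13.7 ± 1.52) apart from the other groups.

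**Figure D1:**
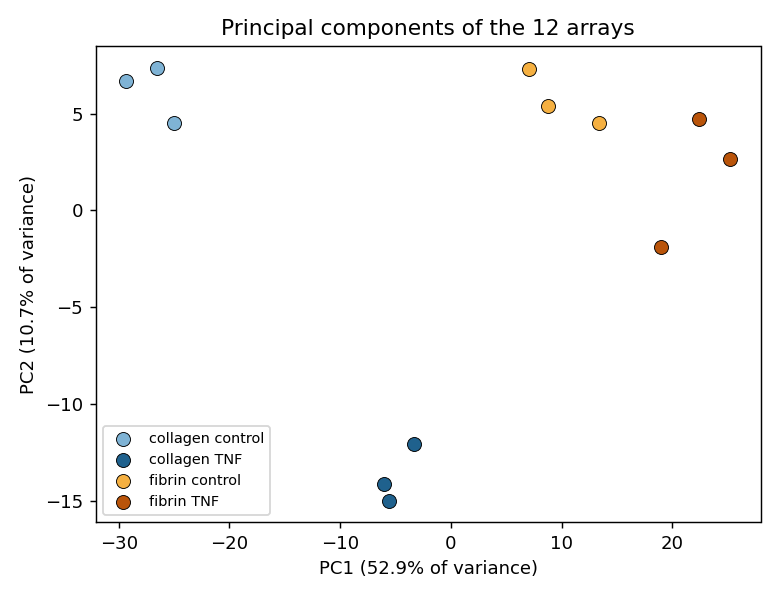
Scores of the 12 arrays on the first and second principal components (arbitrary units, percent of variance on the axes), 1 point per array, coloured by group. The collagen controls lie at the left end and the fibrin TNF arrays at the right end of the first component.

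The first comparison asked what TNF did in collagen. Slpi, a secreted inhibitor of neutrophil proteases, rose 19.6-fold (log2 fold change 4.29 ± 0.16 SE, adjusted p = 4.06e-08), from 6.44 ± 0.11 to 10.73 ± 0.15 (log2, SD, n = 3). Hpx (hemopexin) and Orm1, which encode acute-phase plasma proteins, rose by 4.91 ± 0.56 and 4.21 ± 0.23. Nos2, the inducible nitric oxide synthase, rose by 3.44 ± 0.14 and the stromelysin Mmp3 by 3.29 ± 0.20. Angpt1, a ligand of the endothelial receptor Tie2, rose by 2.30 ± 0.12. Among the largest decreases were Sult1a1, a sulfotransferase (-1.80 ± 0.19), and the aldo-keto reductase Akr1c15 (-1.66 ± 0.10).

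Of 24 measured genes of the NF-kB pathway and its targets, 14 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera adjusted p = 3.49e-17, and adjusted p = 0.0101 with an estimated correlation). Birc3 rose by 1.43 and Nfkbia, the inhibitor that NF-kB itself induces, by 0.70. Of 34 chemokines, 16 rose and 1 fell, or 19 and 1 adjusted over the list alone (adjusted p = 2.13e-15, and adjusted p = 0.0101 with an estimated correlation), led by Ccl9 (3.52), Ccl19 (2.89) and Ccl7 (2.67). The other list calls given here were lost with an estimated correlation. Of 40 interferon-response genes, 21 rose and 0 fell, or 27 and 0 adjusted over the list alone (median log2 difference 0.48, adjusted p = 3.49e-17, and adjusted p = 0.173 with an estimated correlation), among them Cxcl11 (2.27) and Mx1 (1.75). Of 37 genes of hypoxia and glycolysis, 11 rose and 0 fell, or 18 and 0 adjusted over the list alone (median 0.25, adjusted p = 7.93e-11, and adjusted p = 0.173 with an estimated correlation), with Adm at 1.49 and the lactate transporter Slc16a3 at 1.01.

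Of 27 smooth muscle contractile genes, 0 rose and 9 fell in collagen with TNF, or 1 and 13 adjusted over the list alone (median -0.16, adjusted p = 4.05e-06, and adjusted p = 0.239 with an estimated correlation), including Tagln (-0.83) and Mustn1 (-1.16). Of 22 fibroblast markers, 4 rose and 9 fell, or 5 and 11 adjusted over the list alone (adjusted p = 0.00234, and adjusted p = 0.140 with an estimated correlation), with Cygb at -0.97 and Dpt at -0.83. The growth factor gene Igf1 fell (-1.31) and Hgf rose (1.39). In all, 912 of 14324 genes passed, 468 higher and 444 lower, but 570 higher and 608 lower with a trended and robust prior, 584 and 625 with array weights, and 569 and 584 without the 33.3% of genes of lowest mean. Without collagen control replicate 2 or 3 the count was 601 or 568, and without collagen TNF replicate 1 or 2 it was 589 or 568. Of the 41 lists 20 were called, against 13 with the replicate number as a block within each matrix.

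The same question in fibrin gave other leading genes. Cd69, an early activation antigen of leukocytes, rose 4.9-fold (log2 fold change 2.29 ± 0.21 SE, adjusted p = 1.04e-04), and Sele, the endothelial adhesion molecule E-selectin, rose by 1.79 ± 0.13, from 6.53 ± 0.11 to 8.31 ± 0.12 (log2, SD, n = 3). Il6 rose by 1.68 ± 0.23 and Ccl5 by 1.63 ± 0.20. Il6 was higher with TNF in collagen too, at 7.53 to 7.92 (log2) on the TNF arrays against 5.59 to 6.39 on the control arrays. Car9, the carbonic anhydrase induced by hypoxia, fell 6.14-fold (-2.62 ± 0.33, adjusted p = 8.78e-04), the hydroxysteroid dehydrogenase Akr1c14 fell (-2.35 ± 0.15), and Cxcl12 fell (-1.30 ± 0.15).

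Of 24 NF-kB genes, 10 rose and 0 fell in fibrin, or 13 and 2 adjusted over the list alone (adjusted p = 7.97e-09, and adjusted p = 0.0401 with an estimated correlation), with Birc3 at 0.93 and Nfkbia at 0.74. Of 34 chemokines, 7 rose and 1 fell, or 14 and 1 adjusted over the list alone (adjusted p = 1.68e-08, and adjusted p = 0.0401 with an estimated correlation). Of 28 antioxidant and stress genes, 7 rose and 2 fell, or 11 and 2 adjusted over the list alone (adjusted p = 8.89e-08, and adjusted p = 0.0401 with an estimated correlation), with the cystine transporter Slc7a11 at 1.10 and Nqo1 at 0.98. Of 37 other extracellular matrix genes, 0 rose and 4 fell, or 0 and 9 adjusted over the list alone (adjusted p = 4.38e-08, and adjusted p = 0.0401 with an estimated correlation). Of these, the proteoglycan gene Omd fell (-0.72, adjusted p = 0.0130), with adjusted p = 0.0635 without fibrin control replicate 2 and 0.0815 when only the fibrin arrays were fitted. Of 22 fibroblast markers, 1 rose and 6 fell, or 1 and 11 adjusted over the list alone (adjusted p = 1.27e-06, and adjusted p = 0.0401 with an estimated correlation). Of 37 genes of hypoxia and glycolysis, 1 rose and 5 fell, or 2 and 16 adjusted over the list alone (median -0.17, adjusted p = 1.68e-08, and adjusted p = 0.305 with an estimated correlation). In all, 448 genes passed, 237 higher and 211 lower, but more were lower in several alternatives, such as median centring (212 higher and 240 lower) and the fits without fibrin control replicate 1 (214 and 247) or fibrin TNF replicate 2 (252 and 287). The count was 230 when only the fibrin arrays were fitted, 242 or 237 without fibrin control replicate 2 or 3, and 255 or 287 without fibrin TNF replicate 1 or 3.

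Across genes, which are not independent replicates, the TNF effects in collagen and fibrin had a Pearson r of 0.37 and a Spearman rho of 0.21, and they share no array. Higher in both matrices were 108 genes, against 7.74 for independent lists, and lower in both were 78, against 6.54, while 8 genes were called in opposite directions. Genes called higher in collagen had a median effect of 0.59 there and 0.17 in fibrin, and genes called higher in fibrin had 0.51 there and 0.28 in collagen; choosing genes in 1 matrix favours the value in it. Nfkbia and Icam1 rose in both matrices, with log2 fold changes of 0.70 and 0.82 in collagen and 0.74 and 0.53 in fibrin.

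**Figure D2:**
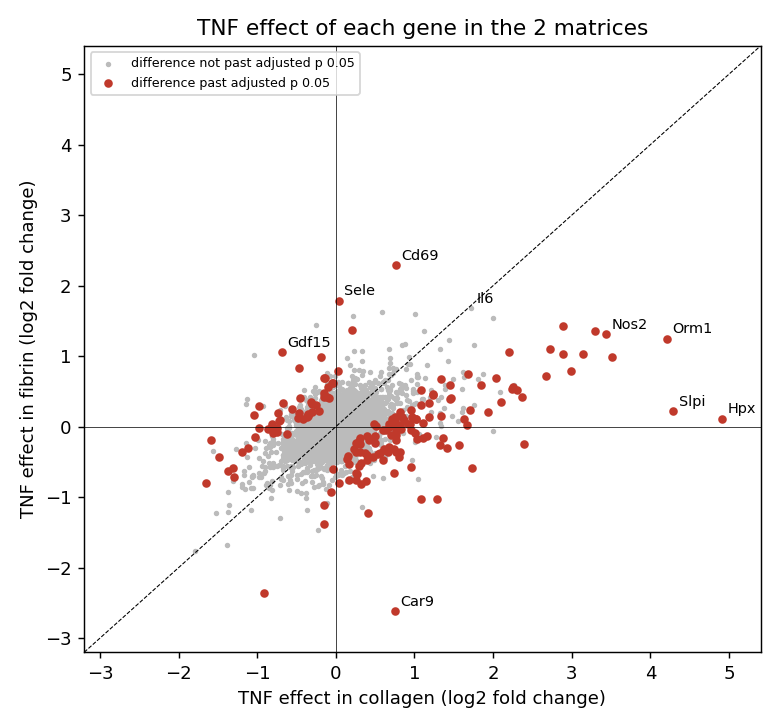
Log2 fold change of each of 14324 genes with TNF in collagen (horizontal axis) and in fibrin (vertical axis), with the line of equal effects dashed and genes whose effects differ at an adjusted p under 0.05 in red. Slpi and Hpx lie far right near 0 on the vertical axis, and Car9 lies lowest.

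Fibrin was then compared with collagen without TNF. Interferon-response genes were far higher in fibrin, where Mx1, an antiviral GTPase, was 29.6-fold higher (log2 difference 4.89 ± 0.27 SE, adjusted p = 2.56e-07; 6.29 ± 0.63 in collagen and 11.17 ± 0.05 in fibrin, SD, n = 3). Rsad2 (4.39 ± 0.27), Isg15 (4.08 ± 0.29) and the transcription factor Irf7 (4.06 ± 0.24) were higher too. Orm1 (4.92 ± 0.23) and Hpx (4.91 ± 0.56), which TNF raised in collagen, were higher in untreated fibrin, a comparison that uses the same collagen controls. Lower in fibrin were Igf1 (-2.27 ± 0.13), the clotting factor subunit F13a1 (-2.24 ± 0.17) and the scavenger receptors Cd163 (-2.19 ± 0.25) and Mrc1 (-1.65 ± 0.19), both markers of resident macrophages.

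Of 40 interferon-response genes, 36 were higher in fibrin and 0 lower, or 38 and 1 adjusted over the list alone (median 2.02, adjusted p = 1.88e-57, and adjusted p = 0.0433 with an estimated correlation). Of 24 NF-kB genes, 16 were higher and 0 lower, or 19 and 0 adjusted over the list alone (adjusted p = 1.19e-19, and adjusted p = 0.00806 with an estimated correlation). Of 34 chemokines, 18 were higher and 2 lower, or 19 and 4 adjusted over the list alone (adjusted p = 1.54e-12, and adjusted p = 0.0206 with an estimated correlation), with Cxcl1 at 3.22 and Ccl3 at 2.73. Of 32 interleukins and colony-stimulating factors, 12 were higher and 0 lower, or 12 and 1 adjusted over the list alone (adjusted p = 3.36e-05, and adjusted p = 0.0433 with an estimated correlation), with Csf3 at 3.02, Il1a at 2.99 and Il6 at 2.57.

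Of 42 macrophage and monocyte markers, 4 were higher in fibrin and 14 lower, or 7 and 16 adjusted over the list alone (median -0.14, adjusted p = 3.25e-04, and adjusted p = 0.430 with an estimated correlation). Folr2 (-1.57), Trem2 (-1.40), Lyve1 (-1.28) and Csf1r (-0.82) were lower, while Cd68 differed by -0.16 and did not pass. The decrease was not particular to macrophages: lists of smooth muscle (adjusted p = 9.00e-05), adipocyte (0.00876), fibroblast (0.0321), dendritic cell (0.0321) and Schwann cell genes (0.0349) were called lower in fibrin too, with adjusted p from 0.154 to 0.431 with an estimated correlation. Of 53 ribosomal protein genes, 0 were higher and 19 lower, or 0 and 37 adjusted over the list alone (median -0.22, adjusted p = 1.54e-14, and adjusted p = 0.127 with an estimated correlation). In all, 1510 genes passed, 767 higher and 743 lower in fibrin, against 904 higher and 1082 lower over all probe sets, named or not. After centring each array on the median of all its probe sets, named or not, the split was 1217 higher and 474 lower. After quantile normalization it was 758 and 736.

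With TNF in both matrices, interferon-response genes were again higher in fibrin. Cxcl10, an interferon-induced chemokine, was 12.2-fold higher (log2 difference 3.61 ± 0.27 SE, adjusted p = 6.34e-06), Rsad2 differed by 3.46 ± 0.27 and Mx1 by 3.43 ± 0.27. Cxcl2, a neutrophil attractant, was higher by 3.37 ± 0.19. Car9 (-2.92 ± 0.33), Cd163 (-2.70 ± 0.25), Akr1c14 (-2.63 ± 0.15) and Clec10a (-2.21 ± 0.15) were lower in fibrin.

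Of 40 interferon-response genes, 38 were higher and 0 lower with TNF, or 38 and 0 adjusted over the list alone (median 1.63, adjusted p = 3.74e-56, and adjusted p = 0.0462 with an estimated correlation). Of 24 NF-kB genes, 12 were higher and 0 lower, or 15 and 0 adjusted over the list alone (adjusted p = 1.31e-12, and adjusted p = 0.0288 with an estimated correlation). Of 42 macrophage markers, 3 were higher and 16 lower, or 5 and 20 adjusted over the list alone (median -0.27, adjusted p = 1.13e-10, and adjusted p = 0.152 with an estimated correlation), with C1qc at -1.29 and Mrc1 at -1.87. Lists of lymphatic endothelial (adjusted p = 1.53e-05), fibroblast (8.64e-04), pericyte (0.00308), endothelial (0.00637) and smooth muscle genes (0.0350) were called lower too, of which the lymphatic list alone was called with an estimated correlation (adjusted p = 0.0288, the others 0.0575 to 0.583). Of 27 fibrillar and other collagen genes, 0 were higher and 10 lower, or 0 and 13 adjusted over the list alone (adjusted p = 1.35e-08, and adjusted p = 0.192 with an estimated correlation), including Col3a1 (-0.67) and Col12a1 (-0.84). In all, 1173 genes passed, 652 higher and 521 lower in fibrin. The split was 880 higher and 387 lower after median centring, and 575 and 565 after quantile normalization. The matrix effects with and without TNF share no array and had a Pearson r of 0.661 across genes, and 332 genes were higher in fibrin in both, against 34.9 for independent lists. The count of calls with TNF was 727 without collagen TNF replicate 3 and 768 without fibrin TNF replicate 1.

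**Figure D3:**
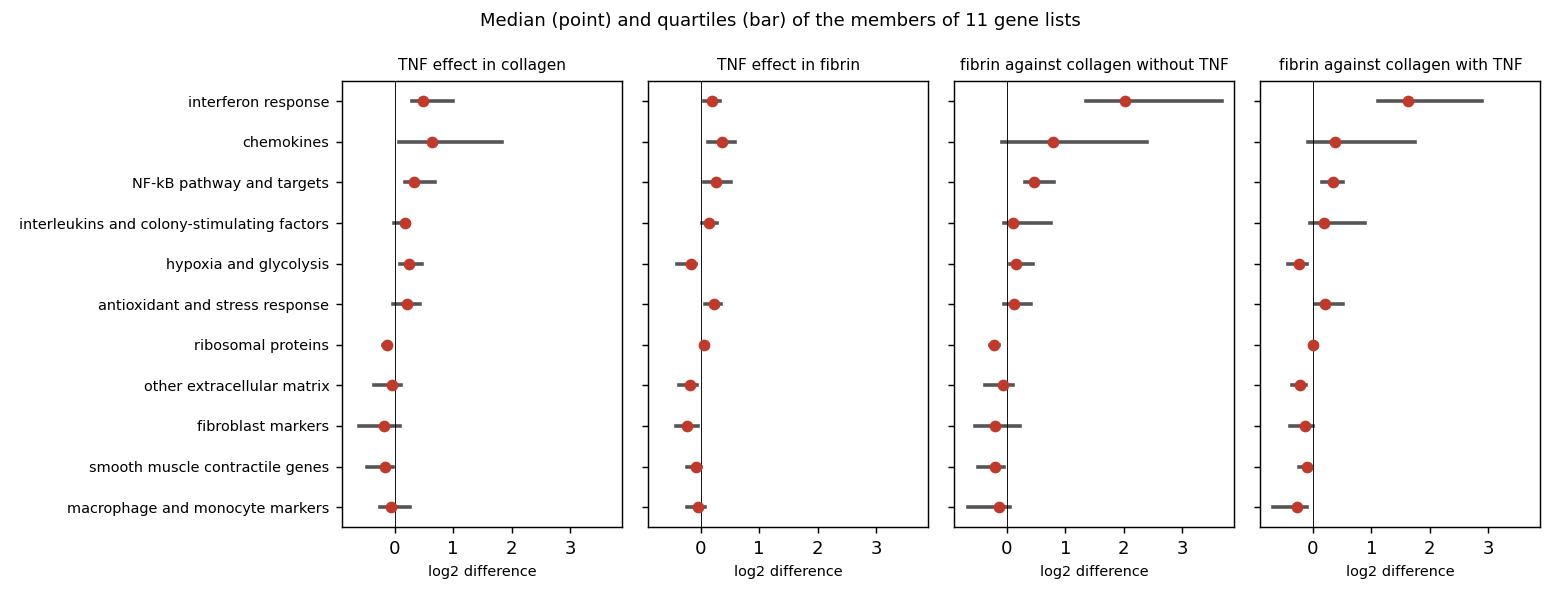
Median (point) and quartiles (bar) of the log2 differences of the measured members of 11 gene lists, 1 panel per comparison on a shared scale. The interferon-response list has medians of 2.02 and 1.63 in the comparisons of fibrin with collagen.

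The difference of the TNF effect between matrices was tested last. Slpi rose with TNF in collagen but had a log2 fold change of 0.22 in fibrin, a difference of -4.07 ± 0.23 SE (adjusted p = 5.10e-06). Slpi already lay at 9.75 to 9.96 (log2) on the fibrin control arrays, above every collagen control array. Its level in untreated fibrin thus forms part of this difference. Hpx (-4.80 ± 0.79), Orm1 (-2.96 ± 0.32), the chemokine gene Ccl9 (-2.53 ± 0.24), the complement gene C3 (-2.32 ± 0.23) and Nos2 (-2.13 ± 0.20) had lower TNF effects in fibrin. Angpt1 (-1.78 ± 0.17), Mmp3 (-1.94 ± 0.29) and Mmp9 (-1.71 ± 0.26) did so as well. Hpx, Orm1 and Angpt1 were also higher in untreated fibrin than in untreated collagen. For them too that level forms part of the difference. For Car9 the difference was -3.36 ± 0.46. Sele (1.75 ± 0.18), the stress cytokine gene Gdf15 (1.74 ± 0.17) and Cd83 (1.18 ± 0.15) had higher TNF effects in fibrin.

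Of 37 genes of hypoxia and glycolysis, 0 had a higher and 8 a lower TNF effect in fibrin, or 0 and 25 adjusted over the list alone (median difference -0.52, adjusted p = 1.15e-23, and adjusted p = 0.0931 with an estimated correlation), among them Slc16a3 (-1.10) and the phosphofructokinase gene Pfkl (-0.79). Of 34 chemokines, 0 had a higher and 9 a lower effect, or 3 and 16 adjusted over the list alone (adjusted p = 8.97e-06, and adjusted p = 0.0931 with an estimated correlation). With an estimated correlation 0 of the 41 lists were called for this difference. In all, 177 genes passed, 53 with a higher and 124 with a lower effect in fibrin, where higher and lower are signed. Of the 124, 101 were also called higher by TNF in collagen, and 27 were called lower by TNF in fibrin. Of the 53, 34 were called lower by TNF in collagen, and 18 were called higher by TNF in fibrin. A lower effect can thus be a weaker rise or a stronger fall, and a higher effect a weaker fall or a stronger rise. Of the 10 + 10 genes of largest difference, 6 lost their call in at least 1 fit with an array left out. The count was 339 with a trended and robust prior, 294 without the 33.3% of genes of lowest mean, 276 with the replicate number as a block, 117 or 103 without collagen TNF replicate 1 or 2, and 112 without fibrin control replicate 2. The genes with a higher effect numbered 29 without collagen control replicate 2, 31, 22 or 30 without collagen TNF replicate 1, 2 or 3, 33 or 30 without fibrin control replicate 1 or 2, and 127 with the trended and robust prior, and those with a lower effect outnumbered them each time.

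**Figure D4:**
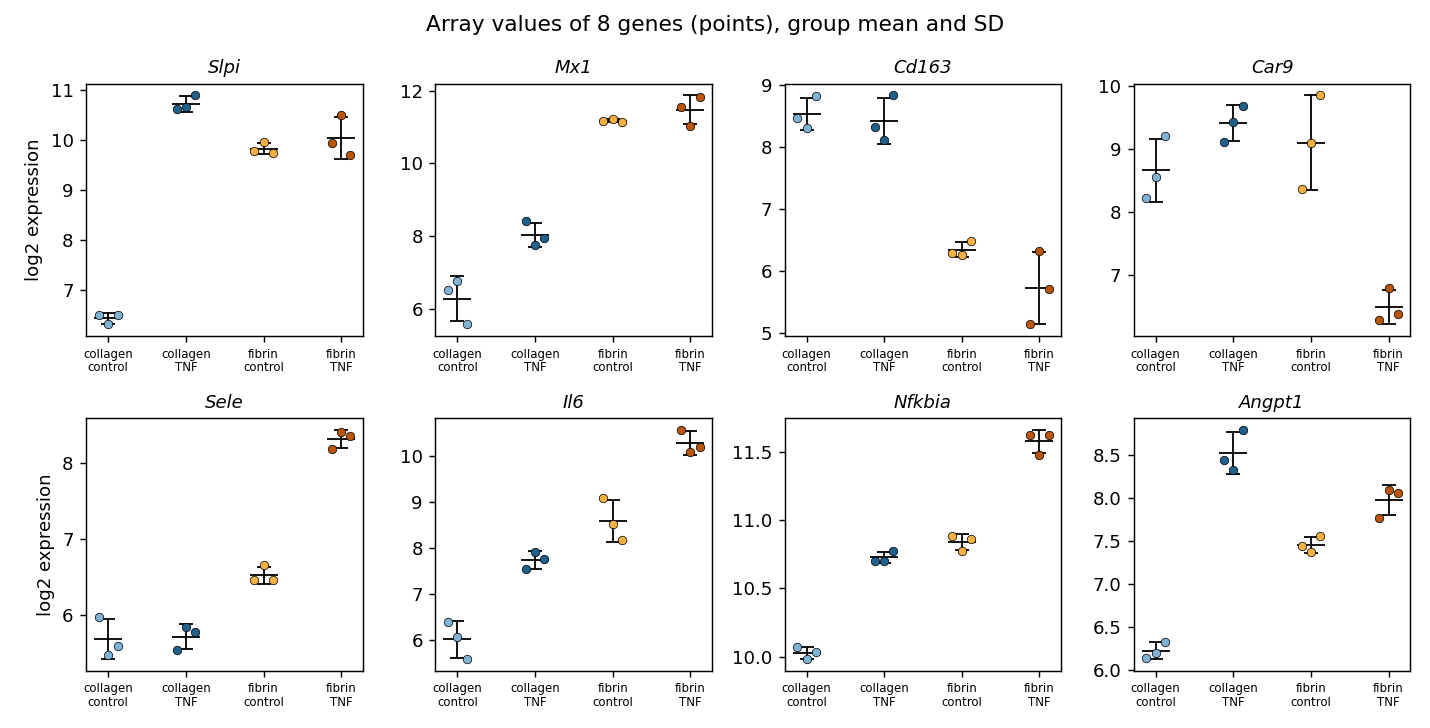
Log2 expression of 8 genes on each array (points) with group means and SD (bars), 3 arrays per group. Slpi lies at 6.44 in collagen control and near 10 in the other groups, Mx1 is highest in both fibrin groups, and Car9 is lowest in fibrin TNF.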

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

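Of the tests given here, those on leukocyte markers, gel constituents, signal saturation, levels already raised in untreated fibrin, random lists and splits of the pairs were chosen only after the result was seen. Each result listed at the end drew attention because a test of the difference found unlike TNF effects in the 2 matrices.

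Interferon-response genes were higher in untreated fibrin than in untreated collagen, by a median of 2.02 (log2), with Mx1 and Irf7 among them. If added leukocytes themselves carried this expression, leukocyte markers should rise by about as much. The highest upper quartile among the 5 leukocyte lists was 0.17, which argues against a gain of leukocytes of that size. A few leukocytes acting on other cells need not raise the lists, so the test cannot exclude them. Of the 5 lists the neutrophil markers were called higher (3 of 17 higher and 0 lower, median 0.02, adjusted p = 0.0447, and adjusted p = 0.317 with an estimated correlation), while 14 members did not pass. Leaving out any 1 of the 6 arrays kept the median at 1.93 or above, which argues against a single array. A constituent of the fibrin gel other than fibrin, such as a contaminant that induces interferon, and fibrin itself cannot be told apart, since 0 labels distinguish gel lots or preparations. A response of the aortic cells to fibrin may therefore be 1 of the explanations, which stays a hypothesis.

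More genes had a lower TNF effect in fibrin (124) than a higher one (53), with Slpi, Hpx and Orm1 among the former. The counts are signed and do not sort weaker from stronger responses. Of the 124, 27 were called lower by TNF in fibrin, and of the 53, 34 were called lower by TNF in collagen. Signal saturation would need the 124 genes near the top of the range in untreated fibrin, where 3.23% of them lay. Leaving out any 1 of the 12 arrays kept an excess of at least 45 genes, so neither saturation nor a single array explains the excess. If a level already raised in untreated fibrin left less room for TNF, genes raised by TNF in collagen that were already higher in fibrin should show the smaller effect in fibrin. They did so in 1 of the 3 rotations of the replicate that set the groups. The median effect of the 382 to 393 such genes minus that of the 75 to 86 others was 0.09, 0.10 and -0.01. That test leaves the explanation undecided, because the sign changed between rotations. Their mean of 0.056 lies within their SD of 0.062, but the rotations share arrays, so this SD does not measure the spread between samples. It also took all 468 genes called higher by TNF in collagen, not the 124 of the pattern. The 124 genes had a median level (log2) of 9.13 in untreated fibrin and 9.17 in collagen TNF. They were chosen with these same arrays, which favours a high level in untreated fibrin, so these medians do not decide either. Slpi, Hpx and Orm1 were each higher in untreated fibrin than in untreated collagen. For these genes the level in untreated fibrin thus forms part of the lower TNF effect. Whether that level limited their response to TNF is not decided by these values.

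Genes of hypoxia and glycolysis had a lower TNF effect in fibrin, with a median difference of -0.52 and 8 of 37 members called, Slc16a3 and Pfkl among them. The list was not called with an estimated correlation (adjusted p = 0.0931), so the shift of the list is uncertain. Its median for fibrin against collagen was 0.16 without TNF and -0.23 with TNF. The level in untreated fibrin thus forms part of the lower TNF effect. A single array is not the cause, since the median difference nearest to 0 with 1 array left out was -0.46. Genes of like expression did not share the shift, as 10000 random lists matched on mean expression had a percentile 2.5 of -0.0556 and 0 reached the value of the list, though random lists lack the correlation of its members (0.369). No biological explanation was tested, since no array or label measures oxygen.

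For each of the 4 comparisons of 2 groups, 1 of 10 splits of the 6 arrays, the real one, called as many genes (912, 448, 1510 and 1173), and the highest of the other splits called 0. These splits are too few for a share under 0.05. For the difference of the TNF effect, 2 of 100 drawn splits of the 12 arrays called at least the real 177 genes, the highest other split called 1127 and 96 called 0. These splits decide nothing, since groups mixed from both matrices carry the matrix and TNF effects as spread, which lowers their counts. The split with 1127 kept the real groups whole under exchanged names. Its contrast was both TNF groups against both control groups, which is the TNF effect over the 2 matrices together. Among the 10 splits of the 6 paired TNF differences between the matrices, 1, the real one, called as many genes (208), and the highest other called 0; these too are too few for a share under 0.05.

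The TNF effect differed between matrices for 177 genes. It was lower in fibrin (log2 difference) for Hpx (-4.80), Slpi (-4.07), Car9 (-3.36), Orm1 (-2.96), Ccl9 (-2.53), C3 (-2.32), Nos2 (-2.13), Ccl7 (-1.96), Mmp3 (-1.94), Ccl19 (-1.86), Angpt1 (-1.78), Mmp9 (-1.71), Akr1c14 (-1.44), Slc16a3 (-1.10) and Pfkl (-0.79). It was higher for Akr1c15 (0.86), Cd83 (1.18), Cd69 (1.53), Gdf15 (1.74) and Sele (1.75). These differences are signed and do not give the size of the response. Car9 and Akr1c14 fell with TNF in fibrin, and Akr1c15 fell less in fibrin than in collagen. The call for Cd69 ended without collagen control replicate 2 (adjusted p = 0.0557), collagen TNF replicate 2 (0.0697) or 3 (0.0517), fibrin control replicate 2 (0.0616) or fibrin TNF replicate 1 (0.0731).

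Of the lists, the median difference was -0.52 for hypoxia and glycolysis, -0.37 for the interferon response, -0.37 for chemokines, -0.36 for lymphatic endothelial markers, -0.21 for metalloproteinases and -0.17 for complement. It was -0.15 for the NF-kB pathway, -0.15 for the cell cycle, -0.14 for collagens, -0.12 for the Notch pathway, -0.12 for angiogenic growth factors, -0.10 for sprouting genes and -0.10 for the TGF-beta pathway. It was -0.10 for neutrophil markers, -0.0465 for pericyte markers, -0.0279 for macrophage markers, 0.0619 for oxidative phosphorylation, 0.16 for smooth muscle genes and 0.21 for ribosomal proteins. With an estimated correlation 0 of these 19 lists were called, with a smallest adjusted p of 0.0931. With the replicate number as a block within each matrix, the smooth muscle, macrophage and oxidative phosphorylation lists lost their calls.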

How the results depend on the processing

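Of the alternatives, the replicate block within each matrix was chosen after seeing the data, and the others before. No called list had a median of the other sign after quantile normalization or median centring. Which side held more genes did change. For TNF in fibrin more genes were lower after quantile normalization (222 higher and 232 lower), median centring (212 and 240), without the 33.3% of genes of lowest mean (289 and 301), with a trended and robust prior (312 and 341), with the replicate block (292 and 324) or the block within each matrix (262 and 294), and without fibrin control replicate 1 (214 and 247) or fibrin TNF replicate 2 (252 and 287). The same held for TNF in collagen without the genes of lowest mean (569 and 584), with the trended and robust prior (570 and 608) and with array weights (584 and 625), and for fibrin against collagen without TNF over all probe sets (904 and 1082). With all arrays kept, counts of genes stayed within a factor of 1.5 of the main count except as follows. With at least a 2-fold change required, the counts were 132 for TNF in collagen, 45 for TNF in fibrin, 232 and 162 for fibrin against collagen without and with TNF, and 68 for the difference of the TNF effect, since this setting removes smaller changes. TNF in fibrin had 230 genes against 448 when only the groups compared were fitted, while TNF in collagen had 826 against 912. Both fits have fewer samples to estimate the spread, which need not cost the same share of calls in each matrix. The main fit estimates 1 spread per gene from all 4 groups, and fibrin TNF had the lowest correlation within a group (0.9953). The cause of the fall was not tested. The difference had 294 genes without the 33.3% of genes of lowest mean, where fewer genes were tested. It had 339 with a trended and robust prior and 276 with the replicate block. The cause of these higher counts was not tested. Genes with a higher and a lower TNF effect in fibrin numbered 108 and 186, 127 and 212, and 89 and 187 in these 3 settings, and 11 and 57 with at least a 2-fold change, against 53 and 124.

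Lists called with an estimated correlation numbered 2 of 20 for TNF in collagen, 6 of 19 for TNF in fibrin, 4 of 19 and 4 of 24 for fibrin against collagen without and with TNF, and 0 of 19 for the difference. With fry they numbered 12 for TNF in fibrin and 10 for the difference. With the replicate block within each matrix 13 lists were called for TNF in collagen.

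The replicate block gave 1128 genes for TNF in collagen, 616 for TNF in fibrin, 1824 and 1484 for fibrin against collagen without and with TNF. As a block within each matrix, where the numbers were taken to pair the arrays, it gave 1018, 556 and, for the difference, 208.

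With 1 array left out, some counts fell below the main count divided by 1.5 in every comparison except fibrin against collagen without TNF. None rose above 1.5 times the main count. Counts ranged from 568 to 769 for TNF in collagen and 237 to 539 for TNF in fibrin. The ranges were 1071 to 1298 and 727 to 1196 for fibrin against collagen without and with TNF, and 103 to 246 for the difference. The correlation of the TNF effects across genes ranged from 0.325 to 0.387. Lists called ranged from 17 to 22, 15 to 21, 16 to 21, 21 to 25 and 15 to 19 in the same order. Of the 24 genes named for size in each comparison of 2 groups, 0 lost their call under another setting. They were chosen for large changes and arrays that do not overlap, which favours keeping the call. Omd, named for TNF in fibrin outside this choice, lost its call in some fits. Of the 20 genes for the difference, 4 lost their call under another setting, and 6 did with an array left out. Signal over background was not analysed here, so low values carry no detection limit.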

Other observations

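Of the tests given here, the comparison of the TNF effect in collagen with the difference between untreated matrices, its simulation and the split of the controls were chosen only after the result was seen. Of 27 antigen presentation genes, 13 were higher and 2 lower in untreated fibrin than in untreated collagen, or 13 and 4 adjusted over the list alone (median 0.32, adjusted p = 6.15e-05, and adjusted p = 0.142 with an estimated correlation). Tap1, a peptide transporter, differed by 1.44 ± 0.07 (log2, SE) and the immunoproteasome subunit Psmb9 by 1.29 ± 0.09. With TNF, 14 were higher and 1 lower, or 14 and 3 adjusted over the list alone (adjusted p = 7.24e-05, and adjusted p = 0.112 with an estimated correlation). Of 32 metalloproteinases and inhibitors, 9 rose and 3 fell with TNF in collagen, or 12 and 5 adjusted over the list alone (adjusted p = 0.00248, and adjusted p = 0.140 with an estimated correlation), with Mmp13 at 2.08 and Adamts7 at 1.14.

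Of 31 endothelial cell markers, 0 rose and 1 fell with TNF in collagen, or 0 and 1 adjusted over the list alone, and the list did not pass (median 0.05, adjusted p = 0.860). With TNF in fibrin 1 rose and 1 fell, or 1 and 2 adjusted over the list alone (median -0.06, adjusted p = 0.0430, and adjusted p = 0.592 with an estimated correlation), and in fibrin against collagen with TNF 2 were higher and 3 lower, or 2 and 7 adjusted over the list alone (median -0.15, adjusted p = 0.00637, and adjusted p = 0.517 with an estimated correlation). Of 15 pericyte markers, 0 rose and 2 fell with TNF in fibrin, or 0 and 5 adjusted over the list alone (median -0.27, adjusted p = 6.95e-05, and adjusted p = 0.134 with an estimated correlation). Of 18 cholesterol synthesis genes, 0 were higher and 4 lower in fibrin than in collagen with TNF, or 0 and 15 adjusted over the list alone (median -0.29, adjusted p = 3.95e-07, and adjusted p = 0.259 with an estimated correlation). Of 8 lymphatic endothelial markers, 0 were higher and 3 lower in that comparison, or 0 and 6 adjusted over the list alone (median -0.35, adjusted p = 1.53e-05, and adjusted p = 0.0288 with an estimated correlation), with Lyve1 at -1.21 ± 0.14, a gene that resident macrophages share.

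The effect of TNF in collagen resembled the difference of untreated fibrin from untreated collagen, for genes such as Nos2 and Orm1. Across genes the Pearson r was 0.747, against 0.486 for simulated unchanged groups that share the collagen controls, and the covariance was 0.0618 against 0.00646. Higher in both were 362 genes, against 25.1 for independent lists and 0 in the simulation, and lower in both were 339, against 23.0 and 0. The simulation leaves out the effects and the independent lists leave out the shared controls, so neither gives the overlap expected without a shared effect. With the 3 collagen controls split 1 and 2, so that the differences shared no array, the covariance was 0.0526 to 0.0586 and r was 0.587 to 0.632 over the 6 ways. Part of the excess of genes called in both may come from the shared controls. Between fibrin control and collagen TNF, which share no control, 381 genes differed, 210 higher and 171 lower in fibrin control.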
